A study of Mus musculus with 41 samples.

How the data were processed

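The series holds RNA-seq of mouse cells and tissue that lack KAP1 (gene Trim28) or the KRAB zinc finger proteins ZFP932 and Gm15446, and ChIP-seq of these factors. KAP1 is a co-repressor that KRAB zinc finger proteins bring to transposable elements. The 41 samples were placed in groups by their labels. RNA-seq covered 22 libraries. These were embryonic stem (ES) cells with floxed Kap1 before and after excision (3 and 3), livers of adult mice with and without a hepatocyte-specific excision by albumin-driven Cre (4 and 4, of which 2 male and 2 female each), mouse embryonic fibroblasts (MEF) without and with excision (2 and 2), and ES cell clones edited at Zfp932 and Gm15446 by CRISPR against clones that received a luciferase guide (2 and 2). Per the labels, excision in ES cells and MEF was induced overnight with 1 µM tamoxifen. ES cells were collected 4 days later, and no such interval is given for MEF; whether the WT cells received tamoxifen is not given in the sources used here. Livers came from mice of 8 weeks fasted for 4 h. ChIP-seq covered HA-tagged ZFP932 and Gm15446, induced for 48 h with 1 µg/mL doxycycline in ES cells and in the myoblast line C2C12, and HA-tagged KAP1 put back into KAP1-deficient MEF, with 2 samples per factor and cell type. The inputs were used only through the authors' peak calling.

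Reads were single-end, 100 bp. Per the labels, ES cell and MEF libraries were made with a stranded mRNA kit and liver libraries with an mRNA kit not described as stranded, each from 200 ng of RNA. The authors aligned to mm9, and the submitters' processing notes name Bowtie2 2.2.1, TopHat2 2.0.11, HTSeq 0.6.1, MACS 1.4.2.1 and bedtools without a version, with no role or order. The deposited gene files hold raw read counts per Ensembl gene, with no normalization. The deposited repeat files hold raw read counts per repeat interval of the mm9 RepeatMasker table. How reads with several alignments, reads on overlapping genes and reads in exons were treated, and whether counting used strand, is not given in the sources used here. Counts of gene families, of overlapping or antisense genes and of repeat copies inside exons are therefore uncertain. The deposited peak files hold 1 list per ChIP sample with the peak caller's score, which is at least 50, the value of −10 log10 p at a p of 1e-05.

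Each gene table held 37991 genes, of which 32919 had a symbol in the gene name table and 5072 did not. Summary lines for reads in no gene or in several genes stayed out of all library sizes and tests; reads in no gene were 5.07% to 15.4% and ambiguous reads 0.855% to 4.62% of all counted. The repeat table held 4877087 intervals, of which 3406390 belonged to LTR, LINE, SINE or DNA elements of 993 families. Of all intervals, 97576 carried several names joined into 1 element; these were assigned to the internal part named most often. A copy entered the copy test when the libraries of at least 1 comparison held 10 reads over it together. Repeat copies are named by family and mm9 position, counted from 1. The RefSeq gene table used for names and for chromosome membership belongs to GRCm38.p6, so genes are reported without coordinates, and genes near peaks were not analysed here.

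The 4 knockout comparisons used edgeR 4.0.16 in R 4.3.3. Each was fitted on its own libraries with TMM factors, filterByExpr at a minimum count of 10, the quasi-likelihood test (two-sided) and Benjamini-Hochberg (BH) adjustment; a gene, family or copy was called at an adjusted p under 0.05. Sex was a covariate in liver. Unless another test is named, every adjusted p below is from this test, SE belongs to the log2 fold change, and means are library-scaled counts (CPM) with SD. Repeat counts were tested per family, per copy and for 10 sets of families fixed by name, with library sizes and TMM factors taken from the gene counts. A set held every family whose name began with given letters, so its name is only a label. MERVL also took in all MT2 families. MLV was set by RLTR4 and MuLV, and so also held families such as RLTR44-int and RLTR46A2. Sex differences and the interaction of sex and genotype were contrasts of a model of the 4 sex-genotype groups. Overlaps of called genes and families were tested with Fisher's exact test (two-sided, BH over all pairs and directions) against n1 × n2 / N. The comparisons share no libraries.

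Gene lists were fixed before the data were examined, as were the groups, designs, named-gene rule and all alternatives except the 2 said to be added later. They held pluripotency, 2-cell-stage, germline, imprinted, KRAB zinc finger, trophectoderm, primitive endoderm, early germ layer, p53 target, interferon response, fibroblast and proliferation genes. Fibroblasts added contractile and TGF-beta response, macrophage, endothelial and epithelial genes. Liver added male-biased, female-biased, xenobiotic, bile acid, lipogenesis, cholesterol synthesis, fatty acid oxidation, acute phase, oncofetal, lymphocyte, stellate, cholangiocyte, hepatocyte and erythroid genes. Each list was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, BH over the lists of a comparison, and again with an estimated correlation. Named genes were the targeted genes and the osteocalcin genes, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 whose groups did not overlap (predicted genes and clones left out), and up to 4 called members per list by smallest adjusted p. For sex contrasts they were the 6 smallest adjusted p values, for families the 6 largest rises and 4 largest falls, and for copies the 4 largest rises and the 3 largest rises under a peak. Names outside this rule are said to be chosen after their values were seen. Single genes of 2 liver lists are not reported here.

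A fold against a group with 0 reads is a lower bound against a floor of 3 reads over that group. With 1 to 3 reads the ratio is given with its 95% Clopper-Pearson interval. Intervals and floors cover counting error only.

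A reproducible peak was a replicate 1 peak overlapping a replicate 2 peak by at least 1 bp. Overlaps of peak sets and peak midpoints in repeat families were set against 1000 random placements on the same chromosomes (one-sided; smallest possible p 0.001; BH over families with at least 5 peaks), with bedtools 2.31.1, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Tested copies under a reproducible peak were compared with all other copies by camera, BH over 20 tests. Figures used matplotlib 3.10.9.

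All steps were tested on simulated data. The list test used 30 genes changed by 1.5-fold, and the peak steps 300 peaks, of which 100 were placed in a chosen family. The count tests used 200 features changed by 2-fold or 4-fold. The gene test recovered 86% and 96% of them for ES KAP1 knockout (17050 genes), 76% and 95% for liver (15075 genes), 14% and 76% for MEF (13288 genes), and 56% and 89% for the ES ZFP knockout (16027 genes). For the interaction of sex and genotype it recovered 24% and 79% (15651 genes). Unchanged genes were 17 of 218 calls for ES KAP1 knockout, 15 of 201 for liver and 10 of 101 for MEF. They were 26 of 173 for the ES ZFP knockout and 9 of 112 for the interaction. The copy test recovered 34% and 78%, 12% and 65%, 8% and 80%, and 7% and 56% in the same order. Alternatives were DESeq2 1.42.0, its size factors within edgeR, other filters, library sizes from repeats, a replicate block, each library left out, a joint fit of all RNA libraries, a 2-fold minimum, and stricter or looser peak definitions. No pair of libraries of a group held identical counts; the chi-square per degree of freedom between replicates was 4.79 to 797. The labels name each liver sample by sex and its own identifier, read here as separate animals, and each ES ZFP sample as a clone. For the other RNA groups nothing says that replicates came from separate cultures, so their p-values measure only the spread between these samples, which may be technical.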

Results

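The series asks how transposable elements and the KRAB zinc finger proteins that control them act on genes in ES cells and in adult tissue. RNA-seq compared KAP1 knockout with WT in ES cells (3 and 3 libraries), liver (4 and 4 animals) and MEF (2 and 2 libraries), and ES cell clones edited at Zfp932 and Gm15446 with control clones (2 and 2). Reads in genes numbered 35.6 to 43.7 M per library in the ES KAP1 experiment, 40.1 to 59.1 M in liver, 27.5 to 35.3 M in MEF and 49.2 to 65.6 M in the edited clones. Reads over transposable elements were 10.6 to 12.1 per 100 gene reads in WT ES cells and 15.6 to 17.3 after KAP1 loss. They were 5.01 to 6.11 in WT and 5.71 to 6.19 in knockout livers, 2.54 to 2.57 in WT and 2.93 to 2.99 in knockout MEF, and 7.31 to 8.36 in the edited and control clones. ChIP-seq gave peak lists of ZFP932 and Gm15446 in ES cells and C2C12 myoblasts and of KAP1 in MEF, with 2 samples each.

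Trim28, which encodes KAP1, was low in every knockout library. In ES cells it stood at 31.9, 27.5 and 29.4 CPM in the knockout libraries and at 2559, 2488 and 2550 CPM in WT, and fell by 6.42 ± 0.06 (SE) on the log2 scale (adjusted p = 5.56e-15). In liver, where the albumin-driven Cre acts in hepatocytes, the means were 9.05 ± 1.77 and 56.3 ± 2.17 CPM (SD, n = 4 and 4), a fall by 2.64 ± 0.13 (adjusted p = 5.32e-06). In MEF they were 10.0 ± 1.86 and 217 ± 80.6 CPM (SD, n = 2 and 2), a fall by 4.44 ± 0.33 (adjusted p = 4.52e-04). In the edited ES clones, Zfp932 stood at 13.6 and 2.31 CPM against 30.9 ± 0.918 in the controls, and Gm15446 at 13.9 and 0.271 CPM against 22.8 ± 1.57 (SD, n = 2). Neither passed the test (adjusted p = 0.933 and 1.00), and since small edits need not lower a transcript, these levels alone do not check the editing. Trim28 was at 2152 ± 279 CPM in the edited and 1987 ± 166 CPM in the control clones (adjusted p = 1.00). After KAP1 loss in ES cells, Zfp932 rose by 0.62 ± 0.11 (adjusted p = 3.49e-04) and Gm15446 by 1.18 on the log2 scale (adjusted p = 2.84e-06). Neither was called in liver (adjusted p = 0.946 and 0.737) or MEF (0.617 and 0.480).

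ES cells without KAP1 had higher levels of 2-cell-stage genes and p53 targets and lower levels of pluripotency genes. The last list did not pass with an estimated correlation (adjusted p = 0.195). The knockout cells had received tamoxifen, which is not known for WT, and had almost no reads of Y-linked genes. Effects of the drug or of other differences between the cells can therefore not be told apart from KAP1 loss in any of these ES results. Among the largest rises were genes of the Zscan4 cluster, whose products mark a 2-cell-like state. Zscan4f rose by 9.67 ± 0.14 on the log2 scale (37.8 ± 0.391 against 0.0440 ± 0.0173 CPM, SD, n = 3 and 3; adjusted p = 4.80e-14) and Zscan4c from 0.0508 to 38.95 CPM. Zscan4d was higher by a ratio of 1634 (95% counting interval 452 to 13500) and Pramef25 by 482 (165 to 2338), where the WT libraries together held 2 and 3 reads. Of the 19 tested 2-cell-stage genes, all 19 rose, also when adjusted over the list alone (median log2 change 6.98, and 6.98 with 1 gene at its bound, camera adjusted p = 7.45e-30, and adjusted p = 0.0494 with an estimated correlation). Zscan4 genes are near-identical copies, so the split of reads among them is uncertain.

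Of 23 p53 targets, 22 rose and 1 was not called, the same counts as adjusted over the list alone (median 1.15, camera adjusted p = 9.61e-18, and 0.0494 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 43.3 to 159 CPM and Ccng1 from 229 to 626 CPM. Of 27 pluripotency genes, 22 fell, 3 rose and 2 were not called, with the same counts adjusted over the list alone (median −0.84, camera adjusted p = 2.05e-13). Nr0b1, a nuclear receptor of the pluripotency network, fell by 4.37 ± 0.10 (8.82 against 181 CPM), and Dnmt3l, a cofactor of de novo DNA methylation, fell by 1.54 ± 0.04 (294 against 854 CPM). Of 131 KRAB zinc finger genes, 74 rose, 11 fell and 46 were not called, the same adjusted over the list alone (median 0.33, camera adjusted p = 0.0312, and adjusted p = 0.682 with an estimated correlation). Zfp992 rose from 15.3 to 184 CPM and Zfp985 from 7.30 to 86.0 CPM, whereas Zfp57, which keeps imprints, fell from 708 to 311 CPM.

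The other ES lists moved in both directions and were not called by camera. Adjusted over the list alone, 14 of 28 germline genes rose and 7 fell (13 and 7 over all genes, camera adjusted p = 0.522), with Piwil2, a piRNA-pathway protein, at 65.2 against 18.6 CPM and Tex19.1 at 20.4 against 126 CPM. In the remaining lists the counts over all genes and adjusted over the list alone were equal. Of 37 imprinted genes, 19 rose and 13 fell (camera adjusted p = 0.497). Igf2, a growth factor, rose from 42.02 to 273 CPM, H19 from 5.44 to 24.8 CPM, and Meg3 fell from 40.4 to 1.01 CPM. Of 22 interferon response genes, 10 rose and 10 fell, and the median (0.14) differed in sign from the mean (−0.40) and the test (adjusted p = 0.236). The RNA sensor gene Ddx58 fell from 173 to 39.02 CPM and Oas1a from 9.57 to 0.125 CPM, while Bst2 rose from 25.2 to 45.2 CPM. Trophectoderm genes gave 9 rises and 4 falls of 16 (adjusted p = 0.497), with Gata2 at 8.41 against 1.38 CPM and Eomes at 2.88 against 12.2 CPM. Primitive endoderm genes gave 5 and 2 of 15 (adjusted p = 0.740), with Lama1 at 38.4 against 134 CPM. Early germ layer genes gave 5 and 5 of 14 (adjusted p = 0.285), with Fgf5 at 0.115 against 2.41 CPM and Otx2 at 17.8 against 11.2 CPM. Fibroblast genes gave 9 and 3 of 15 (adjusted p = 0.497), with Col1a1 at 16.2 against 5.09 CPM and Col1a2 at 0.523 against 7.78 CPM. Proliferation genes gave 5 and 12 of 27 (adjusted p = 0.270), with Ccne1 at 166 against 270 CPM.

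Of 17151 genes tested in ES cells, 6271 were higher and 6090 lower in the knockout, and 2618 and 956 with at least a 2-fold change. Stmn2, a neuronal microtubule regulator, fell from 234 ± 7.62 to 1.78 ± 0.245 CPM and Cobl from 242 to 5.33 CPM. The Y-linked genes Eif2s3y and Uty were at 1.77% and 2.33% of their WT levels. Genes of chromosome 14 had a median log2 change of 0.57 against −0.12 to 0.12 on the other chromosomes. Of 533 genes tested there, 344 were higher and 113 lower. Without them, the counts were 5927 and 5977, an alternative chosen after seeing the data.

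Retroviral elements of ES cells rose with KAP1 loss, most of all the intracisternal A particles (IAP). IAP reads rose from 1648 ± 69.1 to 25030 ± 881 CPM (SD, n = 3 and 3), a log2 change of 3.92 ± 0.08 (adjusted p = 1.21e-14), and MMERVK10C reads from 275 ± 27.3 to 2513 ± 351 CPM (log2 3.19 ± 0.12). The MERVL set, which joins the element of the 2-cell stage with all MT2 families, rose from 1421 to 4553 CPM. The MLV set, which also holds families such as RLTR44-int, rose from 716 to 1954 CPM, and the MMVL30 set from 175 to 426 CPM. L1Md LINE elements rose from 2941 ± 917 to 6195 ± 1303 CPM (log2 1.08 ± 0.18, adjusted p = 1.97e-04). ETn_MusD (log2 0.22), MMERGLN (0.28) and ORR1 (0.25) were also called higher. With library size taken from repeat reads they were at −0.0659, −0.0144 and −0.0385. That setting places the middle of the repeats near 0 by construction, so these values do not show a fall. MT elements were not called (0.19, adjusted p = 0.0810). Among named families, IAPLTR4_I rose by 5.16 ± 0.30, RLTR46A2 by 5.07 ± 0.27 and MMERVK10C-int by 4.28 ± 0.14 on the log2 scale. RLTR1B-int fell from 4443 to 1678 CPM.

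Of 885 families, 371 were higher and 50 lower, and of 64763 copies, 17984 and 6238. The median family change was 0.28 and that of copies 0.20. Library size from repeat reads places these medians near 0 by construction (−0.0005 and −0.0009). The calls were then 240 and 243 families and 14734 and 10514 copies. LTR families made up 283 of the higher and 27 of the lower families, LINE families 55 and 6, DNA elements 33 and 15, and SINE families 0 and 2 of 37. Of the copies, LTR elements made up 8431 of the higher and 1480 of the lower ones, LINE 3582 and 797, DNA 433 and 252, and SINE 5538 and 3709. Over the chromosomes the SINE copy medians correlated with the gene medians (r = 0.968). Whether copies inside genes follow those genes was not tested. Single copies reached large ratios from no reads in WT. An MMERGLN-int copy on chromosome 17 (46487101 to 46494171, mm9), under a KAP1 peak of MEF, was at least 380-fold higher, an MTD copy on chromosome 2 (112139587 to 112139973) at least 414-fold and an IAPEY4_I-int copy on chromosome 19 (3002370 to 3009705), under a KAP1 peak, at least 281-fold.

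**Figure D1:**
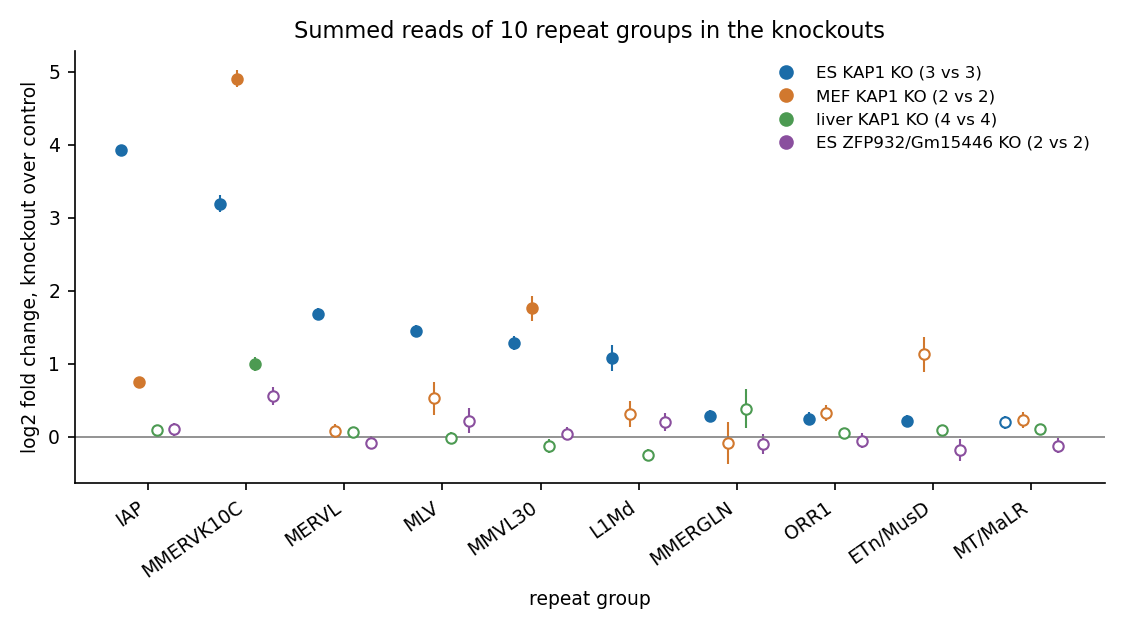
Log2 change (knockout against control, y axis) of 10 sets of repeat families in the 4 comparisons; points are edgeR estimates, bars are SE, and filled points have an adjusted p under 0.05. IAP reaches 3.92 in ES cells without KAP1 and MMERVK10C 4.90 in MEF, while in liver MMERVK10C (0.99) alone is filled and in the ZFP-edited clones none is. ETn_MusD, MMERGLN and ORR1 in ES cells lie slightly below 0 when library size is taken from repeats, which places the repeats near 0 by construction.

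In livers without hepatocyte KAP1, male-biased, interferon, macrophage and stellate cell genes lay lower as lists at the preset correlation between genes. Female-biased and lipid storage genes lay higher, with few members called, and no liver list passed with an estimated correlation (lowest adjusted p = 0.468). Ribosomal RNA made up 2.87% to 6.46% of the repeat reads of knockout livers, 1.07% to 1.61% in WT 1 to 3 and 14.2% in WT 4, and its bearing on the lists was not tested. Rarres1, a retinoid-responsive gene, fell by 7.20 ± 0.46 on the log2 scale (0.364 ± 0.0867 against 71.4 ± 56.9 CPM, SD, n = 4 and 4; adjusted p = 2.77e-05), and Cyp2c23, an arachidonate epoxygenase, by 3.40 ± 0.29 (30.8 against 317 CPM). Catsperg2, a sperm ion channel subunit, rose from 0.0475 to 17.2 ± 10.98 CPM, Mas1, an angiotensin(1-7) receptor, from 0.162 to 25.5 CPM, and Cd28, a T cell co-receptor, from 0.292 to 6.27 ± 0.811 CPM (log2 4.40 ± 0.20, adjusted p = 3.60e-06). Fbxw19 was at least 281-fold higher and Fbxw16 higher by a ratio of 864 (155 to 34180). Bglap3 rose by 2.04 ± 0.25 (3.86 ± 1.39 against 0.998 ± 0.576 CPM, adjusted p = 9.71e-04).

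Of 29 male-biased liver genes, 13 fell, 1 rose and 15 were not called (14 and 2 adjusted over the list alone, median −0.81, camera adjusted p = 5.18e-08, but adjusted p = 0.576 with an estimated correlation). They included Susd4 (log2 −4.58), the urinary protein genes Mup1 (2042 against 6192 CPM) and Mup7 (1373 against 10290 CPM), whose near-identical copies share reads, and Cyp7b1, an oxysterol hydroxylase of bile acid synthesis (7.24 against 284 ± 304 CPM). Of 36 female-biased genes, 9 rose and 3 fell, also adjusted over the list alone (median 0.56, camera adjusted p = 7.44e-04, and adjusted p = 0.694 with an estimated correlation), with the fatty acid transporter Cd36 at 149 ± 41.9 against 29.1 ± 11.5 CPM. Of 24 genes of lipogenesis and lipid droplets, 5 rose and 1 fell, also over the list alone (median 0.08, camera adjusted p = 0.00966, and adjusted p = 0.694 with an estimated correlation), among them Cidec, a lipid droplet protein (15.4 against 2.35 CPM), and Mogat1, an acyltransferase (1.18 against 0.152 CPM).

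Of 29 interferon response genes, 19 fell, 10 were not called and 24 fell when adjusted over the list alone (median −0.60, camera adjusted p = 3.99e-11, but adjusted p = 0.576 with an estimated correlation). Irf7, a transcription factor of the interferon response, was at 19.4 ± 4.60 against 43.3 ± 6.89 CPM and Isg15 at 5.31 against 10.1 CPM. Macrophage markers moved with them, 9 of 14 falling (12 adjusted over the list alone, median −0.55, camera adjusted p = 1.20e-05, and adjusted p = 0.694 with an estimated correlation), as in Vsig4 (16.6 against 26.0 CPM) and Csf1r (30.7 against 45.2 CPM). Of 14 stellate and fibrosis genes, 7 fell (9 over the list alone, median −0.50, camera adjusted p = 1.45e-05, and adjusted p = 0.468 with an estimated correlation), as in Rgs5 (18.9 against 36.2 CPM) and Dcn (62.5 against 101 CPM). Of 118 KRAB zinc finger genes, 17 rose and 101 were not called (17 rose and 2 fell over the list alone, median 0.14, camera adjusted p = 7.44e-04, and adjusted p = 0.576 with an estimated correlation), led by Zfp992 (24.5 against 2.97 CPM) and Zfp791 (6.13 against 1.28 CPM).

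The other liver lists were not called by camera. Of 33 xenobiotic metabolism genes, 7 rose and 5 fell (11 and 5 adjusted over the list alone, adjusted p = 0.261), with Cyp2a5 at 1951 against 589 CPM and Abcc3 at 34.5 against 203 CPM. Of 20 bile acid genes 2 fell, Cyp7b1 and the transporter gene Slco1a1 (2 over the list alone, median 0.01, mean −0.37, adjusted p = 0.597). Of 20 cholesterol synthesis genes 1 fell (1 over the list alone, median −0.23, adjusted p = 0.0880). Of 22 fatty acid oxidation genes 4 rose and 2 fell (5 and 3 over the list alone, adjusted p = 0.427), with Vnn1 at 152 against 54.0 CPM and Ppara at 70.9 against 111 CPM. Of 21 acute phase genes 3 rose and 4 fell (4 and 6 over the list alone, adjusted p = 0.430), with Orm3 at 10.6 against 1.62 CPM and Saa3 at 0.802 against 3.44 CPM. Of 11 oncofetal genes 2 rose and 2 fell (3 and 2 over the list alone, adjusted p = 0.0880), with Spink1 at 2.63 against 0.0971 CPM. Of 28 imprinted genes 5 rose and 5 fell (6 and 5 over the list alone, median −0.10, direction of the test upward, adjusted p = 0.991), with H19 at 1.29 against 0.273 CPM. Of 21 hepatocyte genes 4 rose and 1 fell (6 and 3 over the list alone, adjusted p = 0.430), with Apoa2 at 7480 against 4538 CPM. Of 22 p53 targets 2 rose and 3 fell (also over the list alone, adjusted p = 0.430), with Gdf15 at 1.39 against 3.40 CPM. Of 26 proliferation genes 3 rose and 1 fell (also over the list alone, adjusted p = 0.624), with Tk1 at 38.8 against 22.3 CPM. Of 12 endothelial markers 1 rose (Lyve1, 9.58 against 6.62 CPM, median −0.10), of 7 cholangiocyte markers 1 fell (median 0.25), and of 4 germline genes 1 fell (Brdt, 1.41 against 2.25 CPM), each the same over the list alone and with adjusted p = 0.624. No member was called by edgeR among 14 lymphocyte genes (median 0.22, mean 0.12, adjusted p = 0.624, Ptprc 6.38 against 9.46 CPM, adjusted p = 0.0560) or 5 erythroid genes (adjusted p = 0.985, Alas2 52.8 ± 45.5 against 60.3 ± 62.2 CPM).

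**Figure D2:**
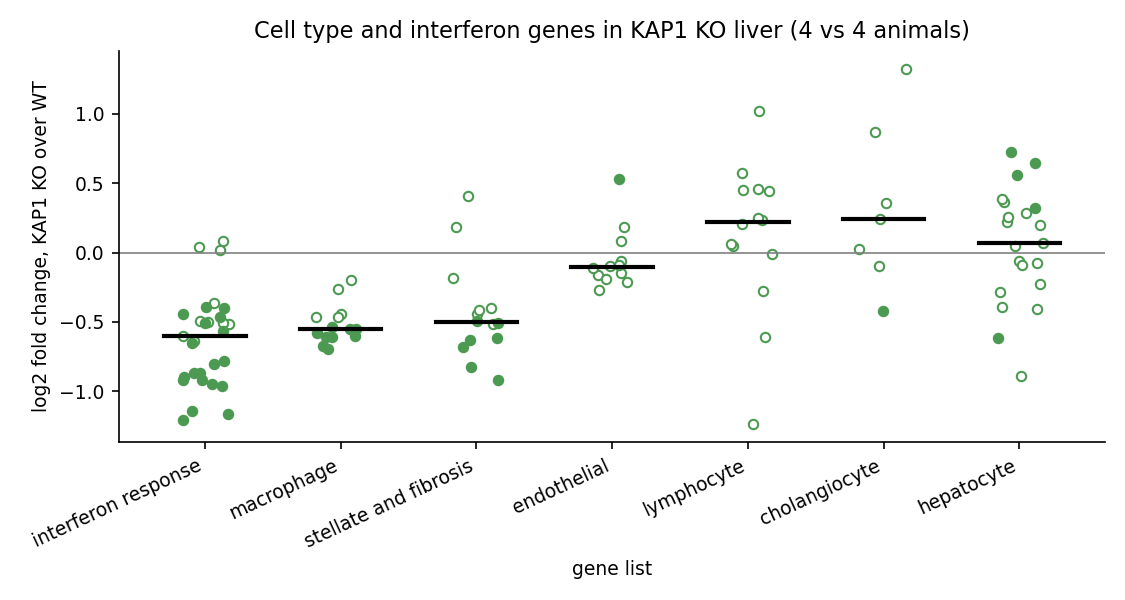
Log2 change (y axis) of each tested member (points) of preset gene lists (x axis) in KAP1 knockout livers. A black line marks the list median, and called genes are filled. Interferon response (median −0.60), macrophage (−0.55) and stellate genes (−0.50) lie below 0, while endothelial markers lie at −0.10.

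Of 15056 genes tested in liver, 1057 were higher and 1067 lower, and 252 and 295 with at least a 2-fold change. Leaving out WT 2, WT 3, WT 4, knockout 1 or knockout 4 lowered a count by over 1.5 times, at most to 508 higher (without knockout 4) and 568 lower (without knockout 1), and a fit without sex called 391 and 360. MMERVK10C was the only one of the 10 repeat sets called, at 254 ± 35.9 against 128 ± 16.0 CPM (log2 0.99 ± 0.09, adjusted p = 1.54e-04), and its internal part MMERVK10C-int rose by 2.76 ± 0.11. RLTR44-int fell from 45.6 to 15.6 CPM. Of 836 families, 66 were higher and 32 lower, and of 29112 copies, 1080 and 642 (714 and 353 without knockout 4). Lower families numbered 18 without WT 2 and 21 without WT 4, and 2 repeat sets were called without WT 1, knockout 2 or knockout 3. An ORR1A0-int copy on chromosome 12 (23487260 to 23488569) was at least 159-fold higher.

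Male and female livers differed from each other, and KAP1 loss narrowed the difference in several sex-biased genes. WT females were higher in 689 and lower in 803 of 15653 genes against WT males, and knockout females in 585 and lower in 386 against knockout males. Of these, 207 female-higher and 185 male-higher genes were shared and 15 had opposite calls. The interaction of sex and genotype was called for 154 genes, 99 with a more positive knockout effect in females. DESeq2 called 269 upward and 229 downward, and a fit with no filter 651 and 504. Cyp2b9, a female-biased cytochrome P450, went from 0.583 to 146 CPM in males and from 544 to 278 CPM in females (interaction −8.92 ± 0.50, adjusted p = 8.68e-05, n = 2 per group). Cyp2d9, a male-biased one, went from 1574 to 2118 CPM in males and from 48.0 to 1179 CPM in females (4.199 ± 0.232). The complement gene C6 went from 389 to 19.4 CPM in males and from 15.2 to 8.72 CPM in females (3.53 ± 0.20). Of the male-biased list, 29 of 30 genes were lower in WT females (median −3.77) and 25 in knockout females (−1.94), and the interaction called 9 upward and 1 downward. Of the female-biased list, 34 of 37 were higher in WT females (5.97) and 24 in knockout females (3.31), and the interaction called 0 upward and 10 downward. KAP1 loss raised 0 and lowered 17 male-biased genes in males (median −1.19), and 6 and 11 in females (−0.004). It raised 14 and lowered 2 female-biased genes in males (1.17), and 9 and 4 in females (−0.11). For the interaction, 154 and 88 genes were called without knockout 1, and 29 and 21 without knockout 3, 46 and 20 without WT 1, 41 and 23 without WT 2 and 31 and 31 without WT 4. Leaving out any WT animal lowered the sex difference in WT, at most to 233 higher (without WT 1) and 254 lower (without WT 4). In knockouts it fell to 369 higher without knockout 1, 247 lower without knockout 2, 160 and 136 without knockout 3, and 261 and 179 without knockout 4.

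In MEF without KAP1, interferon response genes lay higher and fibroblast genes lower as lists at the preset correlation, with 13 of 26 and 8 of 16 members called so, and neither passed with an estimated correlation (adjusted p = 0.540 for both). Ribosomal RNA repeats were at 3624 CPM in knockout and 2364 CPM in WT MEF, and their bearing on the lists was not tested. Of 26 interferon response genes, 13 rose and 13 were not called (15 rose adjusted over the list alone, median 1.21 with 1 gene at its bound, camera adjusted p = 5.65e-09). Ifit1 rose from 2.68 ± 0.583 to 20.9 ± 6.84 CPM (SD, n = 2 and 2; log2 2.96 ± 0.33, adjusted p = 0.00201), Oas1a from 0.250 to 7.72 CPM, and Rsad2, an antiviral enzyme, was at least 62.7-fold higher. Of 16 fibroblast genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone, median −0.85, camera adjusted p = 0.0102), with the collagen gene Col6a1 at 52.3 against 207 CPM and the growth factor receptor gene Pdgfra at 7.53 against 23.1 CPM. Proliferation genes lay higher as a list (median 0.66, camera adjusted p = 0.0169, and adjusted p = 0.786 with an estimated correlation), though edgeR called none of its 27 members, over all genes or adjusted over the list alone (Pcna 516 ± 29.3 against 328 ± 103 CPM, adjusted p = 0.118). The 2 WT libraries lay far apart on several members, as in Plk1 (43.7 ± 46.3 CPM) and Top2a (485 ± 425 CPM), named after their values were seen. The list did not pass without WT 1 (adjusted p = 0.753) or knockout 2 (0.0615).

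The other MEF lists were not called by camera, and their counts adjusted over the list alone equalled those over all genes unless given. Of 125 KRAB zinc finger genes 12 rose and 8 fell (median −0.24; adjusted p = 0.598), with Zfp980 at 92.4 against 12.5 CPM, Zfp600 at 63.1 against 11.7 CPM and Zfp941 at least 60.7-fold lower. Of 25 imprinted genes 4 fell (1 rose and 4 fell over the list alone; adjusted p = 0.549), among them Igf2r (36.9 against 117 CPM) and H19, lower by a ratio of 200 (35.4 to 7925). Of 22 p53 targets 4 fell (adjusted p = 0.318; Perp 40.6 against 118 CPM), and of 15 contractile genes 2 fell (adjusted p = 0.197; Tpm2 70.7 against 174 CPM). Of 3 germline genes Taf7l rose, by a ratio of 30.7 (10.2 to 151; list adjusted p = 0.197), of 2 2-cell-stage genes Usp17la (2.62 against 0.553 CPM; adjusted p = 0.319), and of 3 macrophage genes Csf1r (3.87 against 0.183 CPM; adjusted p = 0.0835). Of 4 endothelial genes Cdh5 rose (10.5 against 0.139 CPM) and Kdr fell (adjusted p = 0.0580). Krt19 was the only epithelial gene tested (92.1 against 129 CPM, adjusted p = 0.212).

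Single genes of MEF lay at or close to 0 CPM in the knockout or in WT. Serpine2, a protease inhibitor, was lower by a ratio of 7935 (2196 to 65520), and Adamts5, a matrix protease, at least 2236-fold lower (0 against 111 ± 31.9 CPM, adjusted p = 1.35e-04). Tsnax was at least 1171-fold lower, and Cdhr2, a protocadherin, rose from 0.163 to 99.8 ± 7.87 CPM (log2 9.26 ± 0.34, adjusted p = 4.02e-05). The median log2 change per chromosome ran from −0.47 (chromosome 4) to 0.76 (chromosome 18). Whether WT MEF received tamoxifen is not known here. Drug effects or other differences between the cells can therefore not be told apart from KAP1 loss in any of these MEF results. Of 13288 genes, 1088 were higher and 1307 lower. A fit on all RNA libraries called 2963 and 3229, and a replicate block 1768 and 2033. The counts were 340 and 438 without knockout 1, 515 and 562 without knockout 2, 1814 and 1988 without WT 2, and 1754 and 2028 with no filter on low counts. MMERVK10C was the most changed repeat set (1920 ± 92.1 against 64.2 ± 5.99 CPM; log2 4.90 ± 0.12, adjusted p = 4.88e-05), followed by MMVL30 (840 against 248 CPM, adjusted p = 0.00558) and IAP (734 against 438.6 CPM, adjusted p = 0.00700). ETn_MusD stood at 246 against 113 CPM (adjusted p = 0.0551). Of 677 families 46 were higher and 5 lower, and the median change of 0.13 became 0.01 with library size from repeats; MuRRS4-int rose from 3.37 to 97.8 CPM. Of 9508 copies 1365 were higher and 467 lower, and DESeq2 called 868 and 126. An MMERVK10C-int copy on chromosome 8 (63216891 to 63223818), under a KAP1 peak of MEF and a Gm15446 peak of ES cells, was at least 76.3-fold higher. Families numbered 86 and 10 without WT 1, 86 and 21 without WT 2, and 71 and 9 without knockout 2, with 10 lower without knockout 1. Lower copies numbered 184 without WT 1 and 305 without knockout 2, and copies 877 and 301 without knockout 1. Of the repeat sets, 5 were called without WT 2 and 6 without knockout 2.

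The response of several repeat sets differed between cell types in a joint fit. The knockout effects on IAP in ES cells, liver and MEF were 3.92, 0.09 and 0.74 (adjusted p of the difference 1.37e-16), on MMERVK10C 3.19, 0.99 and 4.90 (9.21e-12), and on MERVL 1.68, 0.06 and 0.07 (2.65e-10). For ORR1 (adjusted p = 0.164), MMERGLN (0.590) and MT elements (0.665) the difference did not pass. Families higher in all 3 knockouts included MMERVK10C-int, IAPLTR3-int, ETnERV3-int and ETnERV2-int. Liver and MEF shared 10 higher families against 3.64 expected (odds ratio 3.76, Fisher's exact test, adjusted p = 0.0217); ES cells and liver (34 against 28.4, adjusted p = 0.459) and ES cells and MEF (25 against 19.3, adjusted p = 0.338) did not pass. With at least a 2-fold change, ES cells and MEF passed (17 against 4.17, odds ratio 8.10, adjusted p = 4.73e-07), while liver and MEF (4 against 0.885, adjusted p = 0.0537) and ES cells and liver (6 against 2.24, adjusted p = 0.0702) did not.

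Genes shared between knockouts were set against chance. Liver and MEF shared 68 higher genes against 50.2 expected (odds ratio 1.43, Fisher's exact test, adjusted p = 0.0241) and 136 lower genes against 69.9 (2.32, adjusted p = 4.21e-14). ES cells and MEF shared 357 higher genes against 317 (1.23, adjusted p = 0.0134) and 321 lower genes against 454 (0.57, adjusted p = 2.16e-16). ES cells and liver shared 296 higher genes against 321 (adjusted p = 0.125) and 235 lower genes against 336.5 (0.57, adjusted p = 3.96e-13). With at least a 2-fold change, the odds ratios of lower genes turned to 3.38 for ES cells and liver and 2.87 for ES cells and MEF. In all 3 knockouts 26 genes were higher (16.2 expected) and 27 lower (25.1 expected) of 11458. Fbxw19, Cd209c, Cd28 (log2 3.12, 4.40 and 5.51 in ES cells, liver and MEF) and Zfp981 (1.99, 2.07 and 2.21) were among the higher, and Trim28 and the growth factor gene Bmp4 among the lower; these shared genes were named after their values were seen.

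In ES clones edited at Zfp932 and Gm15446, Bglap3, an osteocalcin-related gene, was the only gene called by edgeR with the settings used for all comparisons. It stood at 218 ± 21.1 CPM in the edited and 0.793 ± 0.0630 CPM in the control clones (SD, n = 2 and 2), 274-fold higher (log2 8.10 ± 0.16, adjusted p = 1.71e-04). The related gene Bglap2 was higher by a ratio of 200 (35.6 to 7947) without passing (adjusted p = 0.2001). Bglap3 also rose after KAP1 loss in ES cells (3.27 ± 0.182 against 1.01 ± 0.140 CPM, adjusted p = 3.86e-07). An IAP-d-int copy on chromosome 3 (88173517 to 88176918, minus strand), the chromosome of Bglap3 in GRCm38.p6, went from 0.759 ± 0.0135 to 203 ± 25.2 CPM (log2 8.06 ± 0.28, adjusted p = 1.44e-08) and lay under peaks of all 5 sets. It held 93.1 reads per 100 Bglap3 reads in the edited and 95.3 in the control clones.

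**Figure D3:**
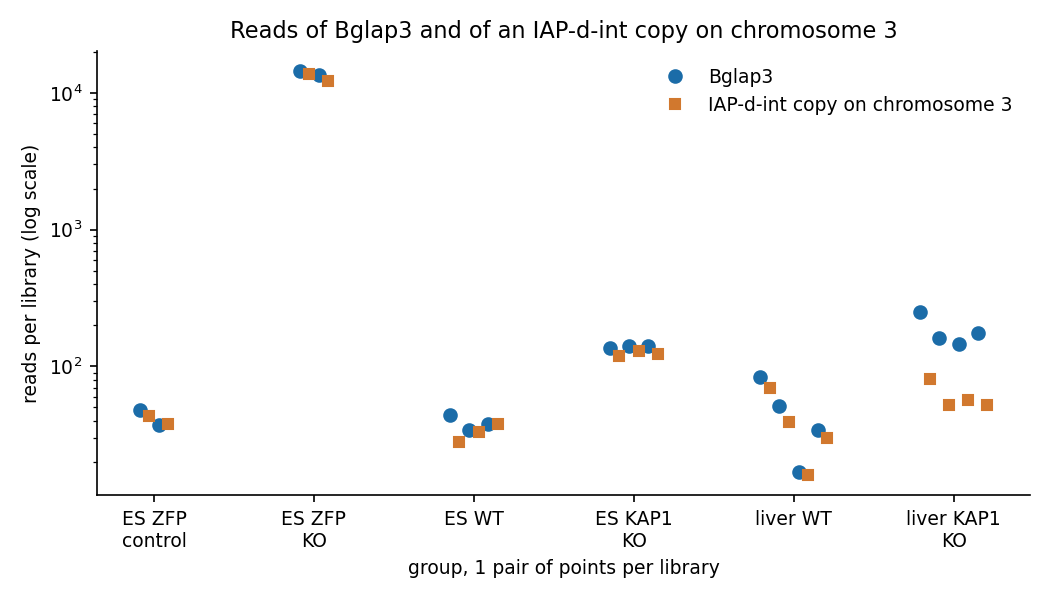
Reads per library (y axis, log scale) of Bglap3 and of the IAP-d-int copy on chromosome 3 in the ES cell and liver libraries; each point is 1 library. In ES cells both rise from 28 to 48 reads in WT and control libraries to 12298 to 14489 in the edited clones, while in knockout livers the copy has 52 to 81 reads and Bglap3 145 to 251.

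With these settings the IAP-d-int family was the only family called higher (234 ± 35.7 against 22.9 ± 8.09 CPM; log2 3.35 ± 0.26, adjusted p = 0.00528), and none was lower; 55 of 803 had an unadjusted p under 0.05 and DESeq2 called 3 higher and 0 lower, and a replicate block 4 and 0. The median family change was −0.11 and became −0.0055 with library size from repeats. None of the 10 repeat sets was called (MMERVK10C 0.55 ± 0.12, adjusted p = 0.569). Of 32745 copies, 19 were higher and 11 lower (45 and 14 with library size from repeats). They included an MMERVK10C-int copy on chromosome 11 (97928691 to 97934383; 6.17 ± 1.05 against 0.233 ± 0.0152 CPM), and IAP-d-int copies on chromosome 11 (106492194 to 106494452), higher by a ratio of 284 (50.6 to 11240), and chromosome 17 (28678644 to 28680881; log2 5.01 ± 0.78). With the settings used for all comparisons edgeR called no gene lower, and 826 of 16065 had an unadjusted p under 0.05. Other settings called more genes, with 242 higher and 147 lower under a replicate block, 67 and 24 in a fit on all RNA libraries, 7 and 3 with no filter, and 73 and 32 by DESeq2. Clones of the same number deviated alike from their groups (r = 0.511). With 2 clones per group the deviations mirror each other, so both pairs give this 1 value. The first principal component of the genes (49.4% of the variance) separated clones 1 (edited 13.7, control 33.5) from clones 2 (−29.5 and −17.7). The fit used for all comparisons holds no term for clone number. Leaving out 1 clone gave 26 and 16 genes (without edited 1), 15 and 13 (edited 2), 15 and 4 (control 1) and 5 and 5 (control 2). For copies these were 154 and 149, 39 and 33, 166 and 165, and 180 and 117, and 7 families were higher without edited 1.

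No list member was called over all genes in these clones, but camera set 4 lists apart (2 without control 1). Primitive endoderm genes lay higher, 8 of 14 adjusted over the list alone (median 1.18; adjusted p = 3.23e-17, but adjusted p = 0.238 with an estimated correlation), with Pdgfra, shared with the fibroblast list, at 3.15 ± 0.507 against 0.757 ± 0.158 CPM (adjusted p = 0.349). Fibroblast genes (1 of 9 adjusted over the list alone, median 0.52, adjusted p = 1.64e-05, and 0.238 with an estimated correlation), p53 targets (1 of 22, median 0.20, 4.41e-05, and 0.789) and germline genes (0 of 23, median 0.26, 9.78e-05, and 0.789) lay higher too. Ei24 stood at 148 against 96.3 CPM and Dmrtb1 at 1.36 against 0.469 CPM. Not called were pluripotency (adjusted p = 0.875; Lin28a 481 against 601 CPM), 2-cell-stage (0.815), imprinted (0.480; 1 lower over the list alone, Nap1l5, by a ratio of 48.1 with an interval of 8.15 to 1947), early germ layer (0.480; Kdr 2.33 against 1.35 CPM), interferon response (0.480; Oas1a 2.42 against 5.83 CPM) and proliferation genes (0.213; Ccnd1 112 against 154 CPM). KRAB zinc finger genes had a median of −0.09 but a mean of 0.02 and an upward test (0.960; 1 higher over the list alone, Zfp775, 1.41 against 0.0840 CPM). Trophectoderm genes had a median of −0.04, a mean of 0.08 and a downward test (0.960).

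ZFP932 and Gm15446 sat on LTR elements in both cell types and shared IAP-d-int, RLTR44-int and MMERVK10D3_I-int among their families. Reproducible peaks numbered 755 for ZFP932 and 1053 for Gm15446 in ES cells, 169 and 209 in C2C12, and 7809 for KAP1 in MEF. These were 35.01% to 82.9% of replicate 1 peaks, with 597 against 296 peaks in the replicates of Gm15446 in C2C12 as the least even pair. Peak midpoints fell in LTR elements for 65.0% and 90.4% of ES cell peaks of ZFP932 and Gm15446, 78.1% and 88.5% in C2C12 and 66.2% of KAP1 peaks, against 11.2% to 11.5% in random placements (permutation test, p = 0.001 each, the smallest possible). Among ES cell peaks, 401 of ZFP932 overlapped Gm15446 peaks (53.1% and 38.1% of the sets; 0.390 expected, permutation test, p = 0.001), and in C2C12 98 did (58.0% and 46.9%). Of C2C12 peaks, 82.2% of ZFP932 and 95.2% of Gm15446 overlapped the ES cell peaks of the same factor. KAP1 peaks of MEF overlapped 21.7% and 20.4% of the ES cell sets and 48.5% and 53.1% of the C2C12 sets, each with p = 0.001 in the permutation test, and 63 peaks were shared by all 5 sets.

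IAP-d-int held 13.8% and 9.21% of ZFP932 and Gm15446 peaks in ES cells and 24.9% and 20.1% in C2C12. RLTR44-int held 11.4%, 10.1%, 15.4% and 21.5%, and MMERVK10D3_I-int 10.9%, 7.502%, 20.7% and 13.9%. MMERVK10C-int was more frequent under Gm15446 (23.0% in ES cells) than under ZFP932 (4.64%), as were IAPEY3-int (17.1% and 0.662%) and IAPEy-int (15.8%, with fewer than 5 ZFP932 peaks), differences that were not tested. KAP1 peaks lay most often on IAPEz-int (41.1%, 78.4-fold over random placement). L1Md_T held 4.32% of them (2.45-fold), and L1Md_A 1.24 times the expected number (adjusted p = 0.0268), which turned to 0.295 times at a peak score of 100 or more.

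**Figure D4:**
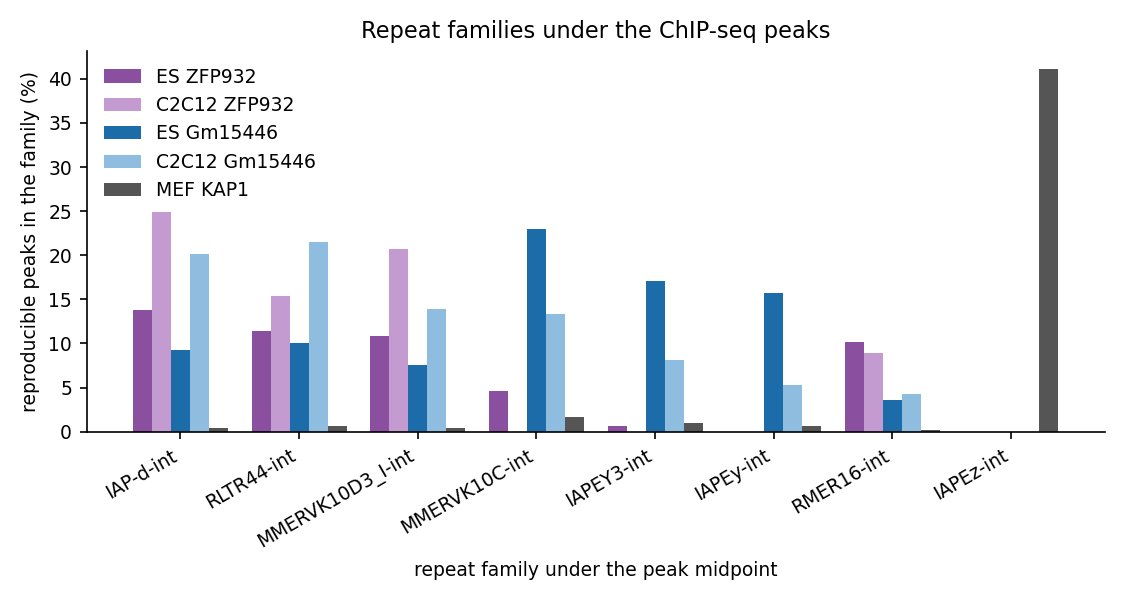
Percent of reproducible peaks (bars, axis from 0) whose midpoint lies in a family, for 5 peak sets; families with fewer than 5 peaks in a set have no bar. IAP-d-int, RLTR44-int and MMERVK10D3_I-int hold peaks of both zinc finger proteins in both cell types, and IAPEz-int holds 41.1% of KAP1 peaks.

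Tested repeat copies under peaks moved in the knockouts. Only copies with enough reads in the compared libraries were tested. A copy without reads in the controls entered only through its reads in the knockout, so it could only rise. Bound copies without reads in either group were not counted. The shares and tests below therefore describe tested copies and depend in part on this filter, which also applied to the other copies. In the edited clones, 8 of 62 tested copies under ES cell ZFP932 peaks rose and 7 of 101 under Gm15446 peaks, against 0.0337% and 0.0368% of other copies. The camera adjusted p was 3.90e-40 and 1.91e-60, and adjusted p = 0.0164 and 0.0324 with an estimated correlation. Under C2C12 peaks 4 of 14 and 6 of 18 rose (adjusted p = 0.0164 for both with an estimated correlation). Under KAP1 peaks 9 of 518 rose (2.16e-11, but adjusted p = 0.193 with an estimated correlation). The sets share most of these rising copies, so the 5 results are not separate. IAP-d-int copies on chromosomes 3, 17 and 9 lay under peaks of all 5 sets. Some rising copies also overlap, as an RLTR10-int copy within an MMERVK10C-int copy on chromosome 11. After KAP1 loss in ES cells, 1991 of 2175 copies under KAP1 peaks rose and 8 fell (median 4.85, and 4.78 with 84 copies at their bound; adjusted p = 0.0164 with an estimated correlation), as did 212 of 229 under Gm15446 peaks (median 4.51, and 4.45 at the bound; 0.0477) and 75 of 102 under ZFP932 peaks (5.50e-10, but adjusted p = 0.140 with an estimated correlation). Under C2C12 peaks of ZFP932 and Gm15446, 15 of 20 and 26 of 32 rose (adjusted p = 0.193 and 0.112 with an estimated correlation). Against other copies of the same families in these ES cells, the C2C12 sets did not pass (adjusted p = 0.131 and 0.431). The KAP1 set (median 4.85 against 0.17, adjusted p = 6.42e-88) and the ZFP932 set of ES cells (1.43 against 0.13, 1.11e-19) did. So did the Gm15446 set of ES cells, with a smaller difference (4.51 against 4.34, 0.00990). These other copies, 35489 for KAP1, were pooled over all families with a bound copy and not matched by family. Where bound and other copies differ in their families, the test does not separate binding from family. Of all tested IAPEz-int copies, bound or not, 2025 of 2032 rose. Copies under ES cell Gm15446 peaks also rose in liver (48 of 76, median 4.25) and MEF (112 of 119, median 5.85, and 5.53 at the bound). Both had adjusted p = 0.0164 with an estimated correlation. Binding of Gm15446 in liver and MEF was not measured. Of all tested MMERVK10C-int copies, bound or not, 73 of 84 rose in liver and 260 of 263 in MEF. Against other copies of the same families, pooled as above, both sets lay higher by camera (4.25 against 0.63 and 5.85 against 3.87, adjusted p = 1.72e-04 and 4.37e-06). Copies under the KAP1 peaks of MEF rose in 134 of 243 cases in MEF (1.09e-27, and 0.0353 with an estimated correlation). In liver 40 of 280 rose and 16 fell (4.43e-04, but adjusted p = 0.125 with an estimated correlation). Under ZFP932 peaks 6 of 31 rose in liver (adjusted p = 2.47e-04, and 0.0273 with an estimated correlation) and 3 of 7 in MEF (adjusted p = 0.219). Of the C2C12 sets, 1 of 8 and 1 of 9 rose in liver (adjusted p = 0.245 and 0.409). There the Gm15446 set lay below other copies of the same families, pooled in the same way (median −0.09 against 4.67, adjusted p = 4.37e-06). In MEF 1 of 4 rose (0.409) and 2 of 2 fell (0.0429, but adjusted p = 0.339 with an estimated correlation).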

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

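The tests of liver cell markers, of Y-linked genes, of genes in order along chromosome 14, of chromosome 14 in the other cell types and of reads shared with Bglap3 were chosen only after the results were seen.

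In ES cells without KAP1, genes of chromosome 14 were higher with a median log2 change of 0.57, and Y-linked genes were nearly absent. An extra copy of the whole chromosome predicts an even rise along its length. The test on SINE copies, fixed beforehand, did not decide. The SINE medians of its 3 stretches were uneven (0.2226, 0.79 and 1.15), but met neither the limits set for an extra copy nor those against it. Of 6 stretches of genes the lowest lay 0.3754 below the chromosome median. The largest such distance among 108 stretches of the other autosomes was 0.215. This test of gene stretches, chosen after the results were seen, argues against an even rise of the genes. A copy of part of the chromosome, or a copy together with other changes, was not tested. A rise caused by KAP1 loss in each cell type does not match liver and MEF, where the higher of the chromosome 14 medians was −0.0268. Loss of the Y chromosome predicts that every Y-linked gene falls together, and the highest share kept by one above 1 CPM in WT was 2.729% (Ddx3y), while X-linked homologues kept 78.7% to 125%. Lowering of Y-linked genes by KAP1 loss in each cell type does not match male livers, where the lowest share kept was 82.14% (Uty).

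In the clones edited at Zfp932 and Gm15446, Bglap3, the IAP-d-int copy on chromosome 3 and the IAP-d-int family rose together. Without that copy, which held 86.9% of the family reads in the edited clones, the family change was 0.4822 ± 0.303 (SE; adjusted p = 0.669) instead of 3.35, in line with reads of 1 copy behind the family call. The ratio of copy reads to Bglap3 reads differed by 1.614 times at most among the ES libraries, which goes with the same reads counted for both. A transcript that runs through both, or shared regulation, predicts a steady ratio too and was not tested, since the tables hold no positions of reads. In knockout livers the copy held 33.2 reads per 100 Bglap3 reads, against 82.8 in WT livers, so Bglap3 reads there were not all shared.

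In KAP1 knockout livers, 19 of 29 interferon, 9 of 14 macrophage and 7 of 14 stellate genes were called lower, and none of these lists passed with an estimated correlation (adjusted p = 0.576, 0.694 and 0.468). A lower share of all non-hepatocyte cells predicts a fall of the endothelial, lymphocyte and cholangiocyte markers too. The smallest gap of their medians above the macrophage median was 0.4476, more than the interquartile range of the macrophage markers (0.142). That range is a spread over genes and not over animals. The gap therefore describes the list medians, and whether it exceeds the variation between livers was not tested. Fewer macrophages and a lower interferon response cannot be told apart, because the median of all 29 interferon genes differed from the macrophage median by only −0.0491, less than that range.

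Splits of the libraries that ignore genotype gave few calls. Among 10 splits of the ES libraries, only 1, the real one, gave as many calls as the genotypes (12361 genes, 421 families and 24222 copies, against at most 0 in any other), and 10 splits are too few for a share under 0.05. Among 34 splits of the livers (1 more was not fitted), only 1, again the real one, did. It gave 2124 genes, 98 families and 1722 copies, against at most 1, 1 and 0 in any other. In ES cells and liver every other split mixes the genotypes, so a difference between them widens the spread within its groups and lowers its calls. The low counts of the other splits therefore do not measure how many calls chance gives. Whether something other than KAP1 loss that runs with genotype divides the livers was not tested.

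Some liver samples stood far from the other 3 of their group in 10 of 200 tested pairs of measure and group, where chance gives about 5%. Ribosomal RNA made up 14.2% of the repeat reads of WT 4 (1.07% to 1.61% in the others), and 2.87% to 6.46% of those of the knockouts. Trim28 was at 11.7 CPM in knockout 4 (7.87 to 8.41). In WT livers Fbxw16 was at 0.0270 CPM in WT 2 (0 in the others), H1fx at 0.0187 in WT 4 (0.0810 to 0.0934), Ei24 at 177 in WT 3 (152 to 155), Sult2a3 at 4.41 in WT 3 (0.0187 to 0.731), Ttr at 3640 in WT 2 (4365 to 4501) and the MMERGLN set at 299 in WT 3 (156 to 171). In knockout 1, Meg3 was at 5.28 CPM (3.67 to 3.94) and Vnn1 at 114 (162 to 168).

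The effect of KAP1 loss differed between male and female livers by the interaction test. The difference, female minus male, was 4.86 on the log2 scale for ENSMUSG00000057138, 4.199 for Cyp2d9, −8.92 for Cyp2b9, 3.53 for C6, 1.78 for Dpy19l3 and −3.51 for Acot1. The KAP1 effects on the repeat sets also differed between ES cells, liver and MEF. The widest gap was 3.83 for IAP, 3.91 for MMERVK10C, 1.04 for ETn_MusD, 1.62 for MERVL, 1.89 for MMVL30, 1.47 for MLV and 1.33 for L1Md.

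Some of the remaining repeat classes stood apart from their controls after KAP1 loss, differences that were not tested. In MEF, RC elements were at 1.85 times the WT level (0.733 against 0.397 CPM), from only 27 and 19 reads in the knockout and 11 and 14 in the WT libraries. RNA repeats were at 1.67 times, snRNA repeats at 1.61 times and rRNA repeats at 1.53 times (3624 against 2364 CPM) the WT level. By contrast, tRNA repeats were at 0.516 times (54.5 against 105.5 CPM). In ES cells, satellite reads were 1.59 times the WT level (4713 against 2962 CPM).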

How the results depend on the processing

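The fits without chromosome 14 and without the IAP-d-int copy on chromosome 3 were chosen after seeing the data. Of the counts and main values, 411 kept their direction, side of the threshold or size and 165 moved; of the other values (named genes, families and copies, repeat sets, gene lists, bound sets, overlaps and peak enrichments), 4740 kept theirs, 62 moved, 81 passed the threshold newly, 197 no longer passed and 7 turned direction. The cause of the changes below was not tested, except that stricter filters, fewer classes and a 2-fold minimum leave fewer features by construction. Genes near peaks were not analysed in the knockouts, because the gene table at hand is GRCm38.p6 and the peaks are mm9. Detection of 2-fold changes was lowest in MEF (14% of simulated genes) and 7% to 34% for repeat copies. Overlaps with the edited clones in which the only called gene or family was shared have no finite odds ratio and were not compared between settings.

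With an estimated correlation, the lists called numbered 2 in ES cells and 0 in liver, MEF and the edited clones, and 2 of 5 bound sets passed after KAP1 loss in ES cells. Against other copies of the same families, pooled without matching by family, 3 passed at the preset correlation. With a 2-fold minimum, ES cells gave 2618 and 956 genes (higher and lower), 102 and 11 families and 3171 lower copies, liver 252 and 295 genes and 20 and 5 families, the sex difference 311 and 301 genes in WT and 288 and 179 in knockout livers, and the odds ratios of shared lower genes turned to 3.38 (ES cells and liver) and 2.87 (ES cells and MEF). With library size from repeats, ES cells gave 240 and 243 families and 10514 lower copies, ETn_MusD, MMERGLN and ORR1 turned to −0.0659, −0.0144 and −0.0385, liver gave 3 repeat sets, MEF 11 lower families and the edited clones 45 higher copies. DESeq2 gave 4032 lower copies in ES cells, 10 lower families and 868 and 126 copies in MEF, 73 and 32 genes and 3 higher families in the edited clones, 269 and 229 genes for the interaction, and 8 of 12 gene overlaps past the threshold.

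With a minimum count of 30, copies numbered 8719 and 3698 in ES cells, 640 and 396 in liver, 712 and 247 in MEF, and 4 lower in the edited clones. With LTR and LINE elements only, there were 2307 lower copies in ES cells, 682 and 357 copies in liver, 3 lower families and 196 lower copies in MEF, and 11 and 4 copies in the edited clones. Without the sex term, liver gave 391 and 360 genes, 17 lower families and 691 and 297 copies. With no filter, MEF gave 1754 and 2028 genes, the edited clones 7 and 3, the interaction 651 and 504, and the sex difference 1414 and 1270 in WT and 1454 and 821 in knockout livers. A fit on all RNA libraries gave 2963 and 3229 genes in MEF and 67 and 24 in the edited clones. At a peak score of 100 or more, the reproducible peaks numbered 495 (ZFP932) and 674 (Gm15446) in ES cells, 85 and 94 in C2C12 and 3860 for KAP1, and L1Md_A turned to 0.295 times the expected number. With peaks of either replicate, all 5 bound sets passed in liver, and copies under C2C12 Gm15446 peaks turned upward in MEF (adjusted p = 6.77e-25). Without the IAP-d-int copy, 0 families were called in the edited clones.

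Replicate numbers do not pair the samples as far as the labels say. Own-number correlations were −0.107 to 0.0573 in ES cells (1 of 3 best with its own number) and −0.102 to 0.0464 in liver (2 of 4). They were 0.251 in MEF and 0.511 in the edited clones, with only 2 pairs each. With 2 samples per group, or per sex and genotype in liver, both pairs give the same value by construction. A replicate block gave 530 and 593 genes, 3 repeat sets and 398 lower copies in liver, 1768 and 2033 genes and 13 lower families in MEF, and 242 and 147 genes, 4 higher families, 1 repeat set and 188 and 152 copies in the edited clones.

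Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, liver gave 508 to 1154 higher and 568 to 1072 lower genes, 18 to 35 lower families, 1 to 2 repeat sets, and 714 to 1189 and 353 to 753 copies. MEF gave 340 to 1814 and 438 to 1988 genes, 65 to 86 and 9 to 21 families, 4 to 6 repeat sets, and 877 to 1457 and 184 to 550 copies. The edited clones gave 5 to 26 and 4 to 16 genes, 2 to 5 lists, 1 to 7 higher families, and 39 to 180 and 33 to 165 copies. The interaction gave 29 to 154 and 20 to 88 genes, and the sex difference 233 to 783 and 254 to 875 in WT and 160 to 464 and 136 to 295 in knockout livers.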

Other observations

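In MEF without KAP1 the median change of genes differed between chromosomes. The median log2 change of genes was 0.76 on chromosome 18, −0.47 on 4, −0.44 on 13, −0.38 on 10 and −0.27 on 1, and over the 20 chromosomes the gene medians correlated with those of SINE copies (r = 0.934). The SINE medians of 3 stretches were alike on chromosome 18 (0.77, 0.80 and 0.76) but not on chromosome 10 (−0.30, −0.58 and 0.68), and whether whole chromosomes differ was not tested. In MEF 28 genes were above 5 CPM in all WT libraries and below 0.1 CPM in the knockout, among them Runx3 and Eif5a2, and 1 gene, Eml2, the other way, all named after their values were seen. In ES cells the counts were 0 and 24, in liver 0 and 1 (Catsperg2) and in the edited clones 0 and 0.

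In knockout livers the IAP-d-int copy held 33.2 reads per 100 Bglap3 reads, and 82.8 in WT livers. The zinc finger genes Zfp979, Zfp980, Zfp981 and Zfp987, chosen here after their values were seen, were each called higher in all 3 KAP1 knockouts. For Zfp979 the log2 changes were 0.65 (ES cells), 2.50 (liver) and 1.78 (MEF).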
